A study of Mus musculus with 222 samples.

How the data were processed

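Gene expression was measured in mouse primordial germ cells (PGCs), sorted from embryonic gonads as cells positive for an Oct4-GFP reporter, from Control embryos and from ECKO embryos, in which a Blimp1-Cre driver deletes Eed in PGCs. Per the labels' protocols, bulk RNA was extracted with an RNeasy Micro kit and amplified with the Ovation RNA-seq System V2, and single E12.5 cells were prepared with Smart-seq2. The 8 whole-genome bisulfite libraries of the series were not analysed here.

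The 5 tables used hold deposited counts: whole numbers per gene symbol, with 1 column per bulk library or per single cell and the same 24391 symbols in each. Per the submitters' processing notes, HISAT2, edgeR and the mm9 build were used, with no version, order or role given. The counting program, the annotation and the strand setting are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart, and counts of members of multi-copy families, pseudogenes and other near-identical genes are uncertain.

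Samples were grouped by sex, stage and genotype as labelled. The bulk groups were E11.5 XY (4 Control, 4 ECKO), E11.5 XX (3 Control, 4 ECKO) and E13.5 XY (4 Control, 3 ECKO). The E12.5 groups held 2 embryos for each sex and genotype, with 24 cells from each. 1 XX cell has a title that says ECKO and a genotype label that says wild type, and it was grouped by its title. The p-values measure the spread between libraries or embryos as labelled. Equal replicate numbers did not mark related libraries throughout: after removal of group means, the correlation of a control with the ECKO library of the same number lay between -0.146 and 0.168. In E11.5 XX the libraries numbered 1 (0.0524) and those numbered 3 (0.168) were each other's closest match, so a relation there stays open. Libraries were compared without pairing, and the replicate number was used as a block in an alternative. Replicates of 1 group differed by far more than counting error, with chi-square per degree of freedom between 4.33 and 210.

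All computation started from the deposited counts. Each bulk table was fitted alone in edgeR 4.0.16 under R 4.3.3 with filterByExpr, TMM scaling and the quasi-likelihood F test, and genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. Whether an effect differed between sexes at E11.5, or between stages in XY, was tested with an interaction term over the joined tables. Cells with at least 50000 counts and at least 1500 genes were kept, their counts were summed per embryo, and all 8 embryos were fitted together with sex by genotype groups, since cells of 1 embryo are not replicates. CPM values (counts scaled by library size) of named genes used TMM factors. Summed CPM of marker lists and of the Hox list used total counts alone. In single cells a gene was scored as present at 10 CPM or more, with exact Clopper-Pearson 95% intervals. A share of 0 is given with the share that 3 cells of the total would make, a one-sided limit below the upper end of the two-sided interval drawn in the figure. A fold against a group with no counts was computed against a floor of 3 counts over the group and is given as "at least". Intervals cover the sampling of cells within 1 embryo only, not missed detection or the spread between embryos. Floors cover counting error only, and reads without molecular identifiers are not independent molecules.

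Gene lists, named genes, tests and most alternatives were fixed before the data were examined. Named genes were Eed, the 8 higher and 8 lower called genes of largest fold change with a mean of at least 5 CPM in the higher group, no overlap between groups and a symbol other than a Gm, Rik, LOC, Mir or Snor name, up to 4 called members of each list with the smallest adjusted p, and Stra8, Sycp3, Dazl, Ddx4, Nanos2, Dnmt3l, Nanog, Pou5f1, Sox2, Cdkn2a and Xist in every comparison. For each interaction they were the 5 genes of smallest adjusted p in each direction. The lists cover meiosis, germline genome defence and late germ cell genes, pluripotency and early PGC genes, male germ cell differentiation, Hox genes, other developmental transcription factors, cell cycle inhibitors, proliferation, p53 targets and apoptosis, imprinted genes, Rhox genes, DNA methylation machinery, retinoic acid and BMP response, markers of gonadal supporting, interstitial, endothelial and blood cells, dissociation stress, X-linked genes, and PRC2 subunits and Y-linked genes, the last 2 described gene by gene. Several genes stand on more than 1 list. Of the list members given, Meiosin, Rnf212, Ankrd31, Gcna, Rhox5, Rhox7 and Dnmt3c matched no symbol in the tables. Lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes and, as an alternative, an estimated one. Adjusted p-values of lists are over the lists of 1 comparison.

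Chromosomes came from a reference gene table of assembly GRCm38.p6, a build other than that of the files, used only to tell which genes lie on the X. It gave a chromosome for 24271 of the 24391 symbols, 1063 of them X-linked and 23161 autosomal. The X to autosome ratio of a library is the log2 of the median CPM of X-linked genes over that of autosomal genes, among genes with a mean of at least 5 CPM, and was compared by a two-sided exact permutation test.

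Bulk libraries held between 415291 and 14974853 counts, and the 127 kept cells of the 192 gave 14162553 to 28753681 counts per embryo. Counts with known changes in 200 genes were simulated from the means, library sizes and spread of each comparison. Of the genes changed 4-fold, the test called 73.1% in the design of E11.5 XY, 52.2% in E11.5 XX, 25.4% in E13.5 XY, 5.97% in E12.5 XX and 10.4% in E12.5 XY. Of those changed 16-fold it called 93.9%, 90.9%, 63.6%, 50.0% and 51.5% in the same order, and of those changed 2-fold 20.9%, 10.4%, 1.49%, 1.49% and 2.99%. Calls on unchanged genes were 11 of 136, 8 of 110, 1 of 61, 2 of 40 and 6 of 49, over 5% in E11.5 XY, E11.5 XX and E12.5 XY. An X to autosome shift of 0.5 was recovered as 0.488, 0.564, 0.534, 0.500 and 0.556. With no shift put in, the values were 0.0718, -0.0431, 0.0462, -0.0288 and 0.137 in the same order. Those of E11.5 XY and E12.5 XY were above or near the differences reported below.

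Alternatives were the Wald test of DESeq2 1.42.0, RLE size factors, no filter on low counts, a minimum of 5 CPM, a minimum log2 fold change of 1, the replicate number as a block, each library or embryo left out in turn, other cell filters, cells thinned to 50000 counts, each sex alone at E12.5, other expression minimums and an X-linked share of counts for the X to autosome ratio. Gene counts were compared with those of other splits of the same libraries.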

Results

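The data were 22 bulk RNA-seq libraries and 192 single-cell libraries of mouse PGCs, the embryonic precursors of sperm and eggs. EED is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 on lysine 27, and the series asks what EED does in PGC differentiation. Bulk libraries came from XY embryos at E11.5, when sexual differentiation of the gonad begins, XX embryos at E11.5 and XY embryos at E13.5. The E11.5 XX libraries were the shallowest, with 415291, 1515482 and 3088644 counts in Controls and 7559310, 1323850, 2638850 and 2966355 in ECKO. The E11.5 XY libraries held 8607927 to 14974853 counts, and the E13.5 XY libraries 4903492 to 12425911. At E12.5, 127 cells were kept, 13 to 22 per embryo, with a median of 1310080 counts and 7056 genes. The 65 cells left out had a median of 1717 counts.

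Eed itself, the targeted gene, was lower in each ECKO library or embryo than in any control of its sex and stage. In E11.5 XY it averaged 107 ± 28.2 CPM (SD, n = 4) in Controls and 35.1 ± 13.7 (n = 4) in ECKO, a log2 fold change of -1.62 (SE 0.29, adjusted p = 0.0118). In E13.5 XY it went from 87.8 ± 26.0 (n = 4) to 8.68 ± 5.07 CPM (n = 3), a log2 fold change of -3.33 (SE 0.56, adjusted p = 0.0107), with an adjusted p of 0.0509 when Control 4 was left out. In E11.5 XX the levels were 83.1 ± 6.22 (n = 3) and 22.4 ± 7.23 CPM (n = 4), with a log2 fold change of -1.88 (SE 0.35) that missed the threshold (adjusted p = 0.0567). At E12.5 the levels were 60.6 ± 2.04 and 18.0 ± 5.66 CPM in XX and 46.6 ± 8.43 and 14.4 ± 10.3 CPM in XY (n = 2 each). The fold changes there, -1.75 in XX (adjusted p = 0.354) and -1.70 in XY (adjusted p = 0.738), did not pass the test. Of the 12 PRC2 subunits on the fixed list, all of them tested in both XY comparisons, Eed alone passed over all genes tested in E11.5 XY and in E13.5 XY. Adjusted over the list alone, 1 subunit was higher and 3 were lower at E11.5 XY, and 5 were lower at E13.5 XY. No subunit passed in E11.5 XX over all genes, and 2 were lower adjusted over the list alone.

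**Figure D1:**
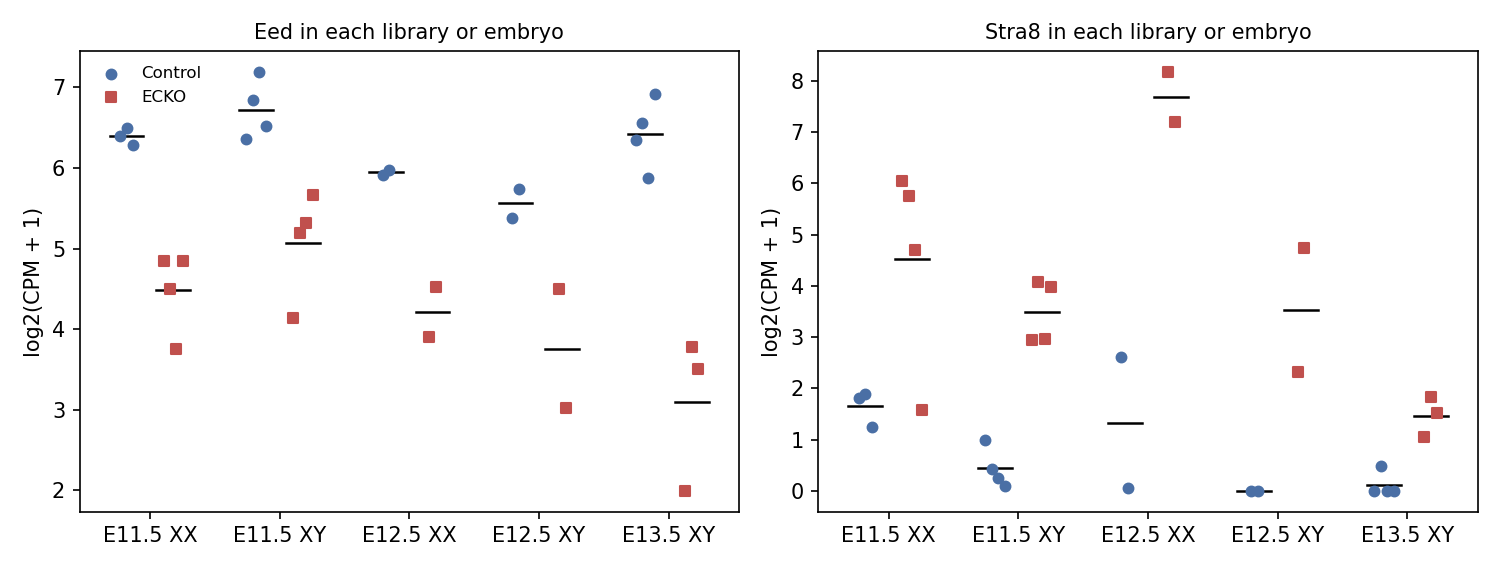
Eed (left) and Stra8 (right) in each bulk library or E12.5 embryo, as log2 of CPM plus 1, by sex and stage. Circles are Controls, squares are ECKO and horizontal lines mark the mean of the plotted values. Eed in ECKO lies below every control of its group, and Stra8 in ECKO lies above every control except in E11.5 XX ECKO 4, at 1.99 CPM.

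The comparison of E11.5 XY ECKO with Control germ cells asks what loss of EED changes in male germ cells at the onset of sexual differentiation. Stra8, a retinoic acid responsive gene that starts meiosis and is normally silent in male germ cells of this age, rose from 0.395 ± 0.405 to 11.1 ± 5.02 CPM (SD, n = 4 each), a log2 fold change of 4.82 (SE 0.89, adjusted p = 0.0127). Other large increases were in Tac2, a neuropeptide gene (6.05, but 2.70 with an adjusted p of 0.392 without ECKO 4, at 55.2 CPM), Ndrg2 (5.11), Fgd5 (5.07), Steap2 (4.84), Fam78b (4.69) and Hand1, a transcription factor of heart and trophoblast (4.65). Tdrd1, a Tudor domain gene of the piRNA pathway, rose from 11.4 to 54.6 CPM (log2 fold change 2.26). The largest decreases were in Gcm1, a trophoblast transcription factor (-3.30), Muc19 (-2.75), Abca4 (-2.69), Rps15a-ps4, a ribosomal pseudogene whose counts are uncertain (-2.65), Ptpn9 (-2.39), AU018091 (-2.15), Serpinb9b (-1.89) and BC048679 (-1.66). All of these genes had no overlap between the 4 Controls and the 4 ECKO libraries. In all, edgeR's quasi-likelihood test called 266 of 12497 genes, 189 higher and 77 lower in ECKO.

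By gene group, germ cell identity genes in E11.5 XY changed in few members. Of 39 tested meiosis genes, Stra8 alone rose over all genes and adjusted over the list alone, and camera did not call the list (adjusted p = 0.848). Sycp3, a synaptonemal complex gene, had a log2 fold change of 0.65 (adjusted p = 0.661). Among 33 genes of germline genome defence and late germ cells, Tdrd1 rose and Dppa4 fell (log2 fold change -0.95), and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.288). The germ cell RNA-binding genes Dazl and Ddx4 had log2 fold changes of 0.12 and 0.02. The pluripotency and early PGC list of 38 tested genes shifted down (camera adjusted p = 0.00511, adjusted p = 0.403 with an estimated correlation). Dppa4 and Klf5 (-1.13) were its members called over all genes, and adjusted over the list alone 2 rose and 7 fell. Nanog (-0.74, adjusted p = 0.138), Sox2 (-0.34) and Pou5f1 (0.79, adjusted p = 0.140) did not pass. The male germ cell differentiation list of 25 tested genes shifted up (adjusted p = 0.000426, adjusted p = 0.170 with an estimated correlation). Tdrd1, Nrp2 (1.76) and Ccnd2, a D-type cyclin gene (1.47), were called, and 8 rose adjusted over the list alone. Nanos2 and Dnmt3l had no counts in any E11.5 bulk library, and Cdkn2a was low in both groups (0.648 and 2.17 CPM).

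Lists of developmental and signalling genes also shifted up in E11.5 XY. The list of 7 tested Hox genes shifted up, and 4 rose adjusted over the list alone (camera adjusted p = 0.00398, adjusted p = 0.272 with an estimated correlation). Of 49 other developmental transcription factors, Hand1 rose, Isl2 (-1.46) and Tbx4 (from 120 to 56.0 CPM) fell, and adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 9.5e-05, adjusted p = 0.181 with an estimated correlation). Of 20 retinoic acid and BMP response genes, those that rose included the retinoic acid receptor gene Rarb (2.93) and Crabp1 (1.61), and 7 rose adjusted over the list alone (camera adjusted p = 9.5e-05, adjusted p = 0.170 with an estimated correlation). In the p53 and apoptosis list of 26 genes, 5 rose over all genes, among them Pmaip1, a pro-apoptotic BH3-only gene (4.27), Psrc1 (2.88), Ccng1 (1.21) and the cell cycle inhibitor Cdkn1a, which went from 64.2 to 145 CPM (1.17, SE 0.19). Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.00127, adjusted p = 0.124 with an estimated correlation). Cdkn1a and Cdkn1c (2.80) were the called members of 7 cell cycle inhibitors, of which 3 rose adjusted over the list alone (camera adjusted p = 0.0208, adjusted p = 0.170 with an estimated correlation). The 33 proliferation genes had no called member on either scale and shifted down as a list (camera adjusted p = 0.00740, adjusted p = 0.138 with an estimated correlation).

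Of 46 tested imprinted genes, Cdkn1c, Plagl1 (2.26), Cd81 (1.53) and Sfmbt2 (1.31) rose in E11.5 XY, and adjusted over the list alone 13 rose and 2 fell (camera adjusted p = 0.00639, adjusted p = 0.272 with an estimated correlation). Of 13 genes of the DNA methylation machinery, the de novo methyltransferase gene Dnmt3b (2.50) and Uhrf1, which recruits DNMT1 (1.38), rose, whereas Tet1 (-0.68) and Trim28 (-0.54) fell. Adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.292). Of 13 Rhox genes, Rhox9 fell (-0.60), 2 fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.0579). None of 6 tested Y-linked genes was called in E11.5 XY or in E13.5 XY by edgeR. Of 460 X-linked genes, 9 rose and 3 fell over all genes, 9 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.876).

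Marker lists of other cells and of handling also moved in E11.5 XY. Supporting cell markers (15 tested) shifted up with 1 gene called, Aard, which fell (-1.38), and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.183 with an estimated correlation). Interstitial markers (15 tested) shifted up with no called member on either scale (camera adjusted p = 0.00972, adjusted p = 0.388 with an estimated correlation). The library ECKO 4 had the highest sums of interstitial and endothelial markers, 559 and 331 CPM, and also the highest Hox sum, 171 CPM against 13.3, 44.9 and 54.3 CPM in the other ECKO libraries. The Control Hox sums were 51.0, 8.67, 16.8 and 8.09 CPM, and overlapped those of the other ECKO libraries. Endothelial (9 tested, camera adjusted p = 0.823) and blood markers (7 tested, camera adjusted p = 0.487) had no called member on either scale. Of 18 dissociation stress genes, Fos (3.06) and Egr1, from 45.5 to 233 CPM (2.36), rose, and 3 rose adjusted over the list alone (camera adjusted p = 0.00972, adjusted p = 0.171 with an estimated correlation).

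The count in E11.5 XY rested on single libraries, with 64, 125, 65, 130 and 162 genes called when Control 2, Control 3, Control 4, ECKO 2 or ECKO 4 was left out, and DESeq2 called 771. Of the 42 named genes called, 16 lost the call under another test, filter or setting and 27 in at least 1 fit with a library left out, among them Stra8 and Tdrd1 without Control 2 (adjusted p = 0.0516 each), whereas Eed, Hand1, Cdkn1a, Pmaip1, Egr1 and Fos kept it under every alternative run. Without ECKO 4, Fgd5 (3.71), Dnmt3b (1.98), Plagl1 (1.53) and Cd81 (1.02) lost the call, and Cdkn1c stood at 1.62.

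The E11.5 XX comparison asks the same of female germ cells. Hand1 rose from 1.75 ± 0.666 (SD, n = 3) to 36.2 ± 14.9 CPM (n = 4), a log2 fold change of 4.53 (SE 0.67, adjusted p = 0.0281), and Tdrd1 rose from 4.52 ± 0.682 to 63.2 ± 9.97 CPM, a log2 fold change of 3.86 (SE 0.42, adjusted p = 0.00478). Adgra2 (3.95), the cyclin gene Ccnd1 (3.93), the cholesterol transporter gene Abca1 (3.54), Serpine2 (3.07), the arginine transporter gene Slc7a1 (2.94) and Amotl1 (2.90) also rose. The glycolytic gene Pfkp (-1.63), the nucleosome-binding gene Hmgn5 (-1.61), Gnai1 (-1.61) and the ribosomal protein gene Rpl29 (-1.19) fell. Each of these genes had no overlap between the 3 Controls and the 4 ECKO libraries. Stra8 did not pass (log2 fold change 4.14, adjusted p = 0.122): 3 ECKO libraries stood at 65.0, 53.1 and 25.0 CPM, and ECKO 4 at 1.99 CPM lay within the Controls (1.36 to 2.73 CPM). In all, 19 of 11058 genes were called, 15 higher and 4 lower.

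Few list members were called in E11.5 XX. Hand1 was the called gene of 35 developmental transcription factors, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 4.0e-05, adjusted p = 0.0938 with an estimated correlation). Tdrd1 was the called gene of 23 male germ cell differentiation genes, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00247, adjusted p = 0.219 with an estimated correlation). It was also the called gene of 30 genome defence and late germ cell genes, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.120). No gene was called over all genes tested in the lists that follow. Retinoic acid and BMP response genes (18 tested, 4 higher adjusted over the list alone) shifted up (camera adjusted p = 0.00154, adjusted p = 0.0938 with an estimated correlation). Imprinted genes (44 tested, 5 higher adjusted over the list alone) did so as well (camera adjusted p = 0.0137, adjusted p = 0.643 with an estimated correlation), as did interstitial markers (13 tested, 0 adjusted over the list alone, camera adjusted p = 0.00800, adjusted p = 0.531 with an estimated correlation). Pluripotency and early PGC genes (37 tested, 1 higher and 2 lower adjusted over the list alone) shifted down (camera adjusted p = 0.00731, adjusted p = 0.740 with an estimated correlation). Meiosis genes (32 tested, 3 higher and 2 lower adjusted over the list alone) were not called as a list (camera adjusted p = 0.882). Nanog (-0.75, adjusted p = 0.338), Sox2 (-0.75), Pou5f1 (0.30), Dazl (0.83), Ddx4 (0.42) and Sycp3 (0.23) did not pass, nor did Xist, at 110 CPM in Controls and 254 in ECKO (1.19, SE 0.85, and -0.06 without ECKO 4).

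ECKO 4 stood apart in E11.5 XX. Its interstitial marker sum was 1416 CPM against 128 to 255 in the other ECKO libraries, and its Hox sum was 353 CPM against 9.82, 24.3 and 44.7. The Control Hox sums were 14.4, 48.8 and 1.62 CPM, a range that held those of the other ECKO libraries. Without ECKO 4, 26 genes were called, and Eed (adjusted p = 0.0278) and Stra8 (adjusted p = 0.00836) passed. The 19 calls rested on every Control: 0 genes were called by edgeR when any of the 3 was left out, and 1 without ECKO 1, whereas DESeq2 called 315 genes from all 7 libraries. Leaving out Control 3 gave 3 called lists in place of 6.

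Changes at E11.5 overlapped between the sexes. Among 10915 genes tested in both, 11 genes rose in both, 0.234 expected by chance (Fisher's exact test, p = 1.2e-17): Abca1, Adgra2, Amotl1, Bend4, Ccnd1, Hand1, Ptprf, Ptprs, Sdc3, Serpine2 and Tdrd1. Gnai1, Hmgn5 and Pfkp fell in both (0.0275 expected, Fisher's exact p = 1.2e-06). Of the genes higher in XY, 98.2% also had a positive fold change in XX. The test of the difference between the sexes called 0 of 14185 genes in edgeR, with 747 at an unadjusted p under 0.05 (709 expected) and 1 gene in DESeq2. It called 1 gene when XY Control 3 was left out. The smallest adjusted p, 0.587, belonged to Cyp51 (difference of log2 fold changes 1.62, SE 0.33) and Fads1 (1.95, SE 0.41), genes of cholesterol and fatty acid synthesis, both more positive in XX.

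**Figure D2:**
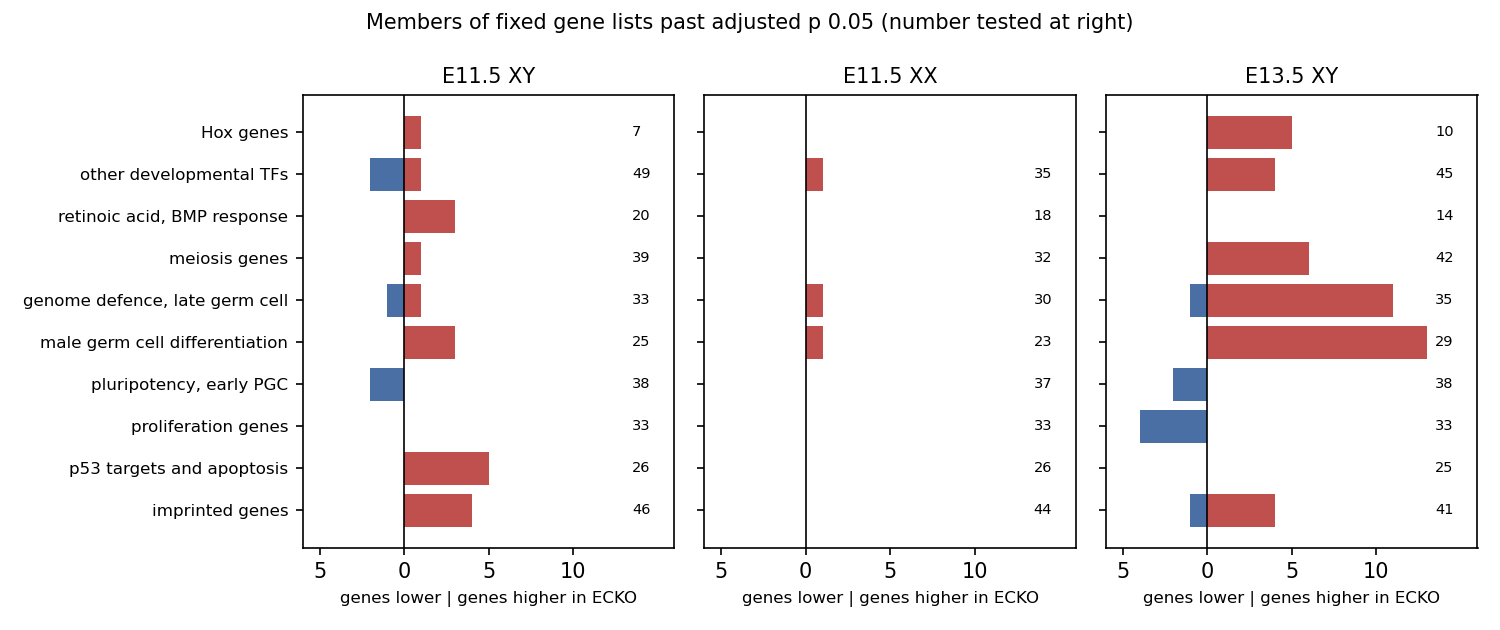
Number of members of 10 fixed gene lists called higher (right of 0) or lower (left of 0) in ECKO at an adjusted p under 0.05 over all genes tested, in the 3 bulk comparisons. Numbers at the right give the members tested, and Hox genes are not shown for E11.5 XX, where none passed the filter on low counts. At E13.5 XY the male germ cell differentiation list has 13 of 29 members higher.

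Single germ cells at E12.5 show which share of cells carries each transcript. Eed itself was still present in 6 of 13 and 6 of 13 XX ECKO cells and in 13 of 18 and 6 of 18 XY ECKO cells. The Control shares of Eed were 12 of 14 and 15 of 16 cells in XX and 10 of 13 and 20 of 22 in XY. Stra8 was present in 13 of 13 cells (100%, 95% CI 75.3 to 100) and 12 of 13 cells (92.3%, 64.0 to 99.8) of the 2 XX ECKO embryos. In the XX Control embryos it was present in 1 of 14 cells (7.14%) and 0 of 16 cells, which allows a share of up to 18.8%. In XY ECKO embryos it was present in 1 of 18 (5.56%) and 4 of 18 cells (22.2%), and in XY Control embryos in 0 of 13 and 0 of 22 cells, which allows up to 23.1% and 13.6%. With cells thinned to 50000 counts, the share with any Stra8 count was 100% and 92.3% in XX ECKO, 14.3% and 0% in XX Controls, 11.1% and 16.7% in XY ECKO and 0% in both XY Controls. Sycp3 was present in 7 of 13 and 8 of 13 XX ECKO cells against 2 of 14 and 0 of 16 in Controls, the latter allowing up to 18.8%. Its XY ECKO shares were 6 of 18 and 2 of 18 cells. The XY Control shares of Sycp3 were 0 of 13, which allows up to 23.1%, and 1 of 22. Pou5f1, a pluripotency gene whose regulatory sequence drives the sorting reporter, differed between embryos of 1 group. It was present in 12 of 13 and 2 of 13 XX ECKO cells and in 5 of 18 and 17 of 18 XY ECKO cells, against 14 of 14, 14 of 16, 13 of 13 and 22 of 22 cells in the Controls. Nanog was present in 5 of 13 and 3 of 13 XX ECKO cells against 11 of 14 and 15 of 16 in XX Controls. The XY shares of Nanog were 7 of 18 and 16 of 18 in ECKO and 13 of 13 and 17 of 22 in Controls. Dnmt3l, a male germ cell cofactor of DNA methylation, was present in 3 of 18 and 2 of 18 XY ECKO cells and in 0 cells of the other 6 embryos, which allows up to 13.6% to 23.1% by embryo. Nanos2, the male germ cell fate gene, was present in 0 of the 127 cells, with the same limits by embryo. Xist, the X inactivation RNA, was present in 1 of 13 cells of 1 XX ECKO embryo, 1 of 18 cells of 1 XY ECKO embryo and 0 cells of the XX Controls, which allows up to 21.4% and 18.8%.

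**Figure D3:**
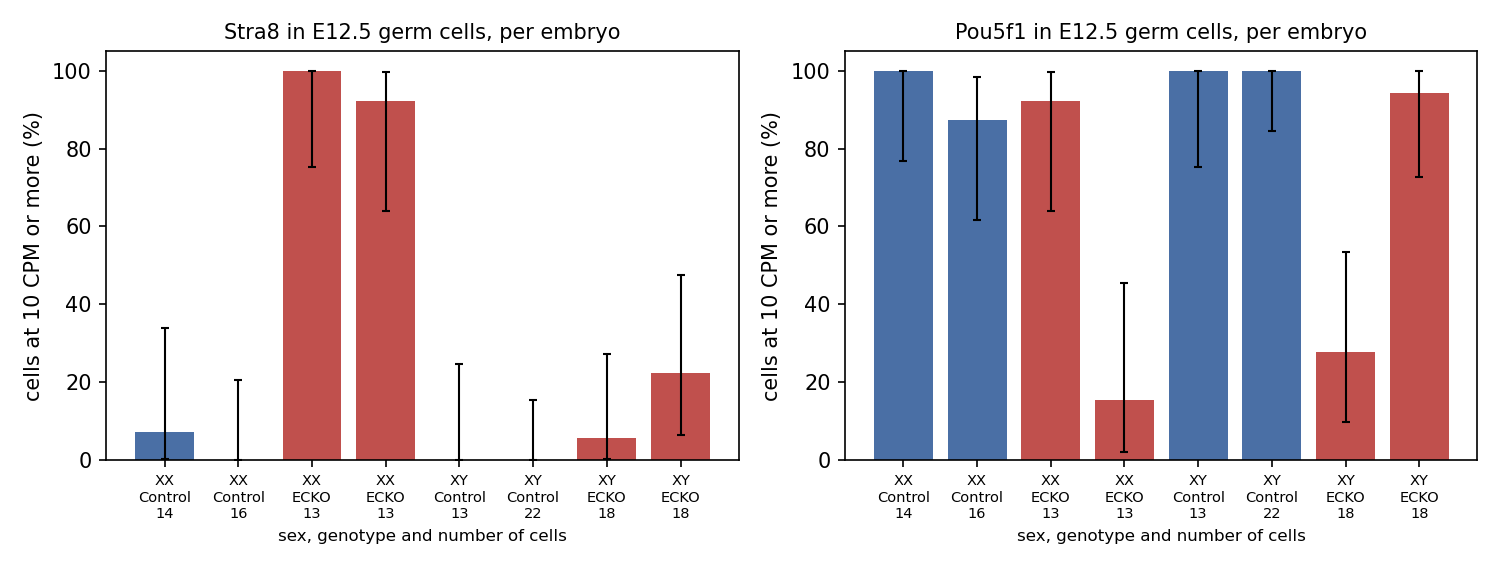
Share of E12.5 germ cells with Stra8 (left) or Pou5f1 (right) at 10 CPM or more, in percent, in each of the 8 embryos, with the number of cells under each bar. Error bars are exact 95% Clopper-Pearson intervals. Stra8 is present in 100% and 92.3% of cells in the XX ECKO embryos and in 7.14% and 0% in the XX Controls.

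With counts summed per embryo, 3 of 13956 genes were called in E12.5 XX and 1 in E12.5 XY (n = 2 embryos per group). In XX, the lipid droplet gene Plin3 (log2 fold change 11.46) and Bin2, a membrane-shaping BAR protein gene (9.44), rose and the kinase gene Jak3 fell from 215 ± 26.7 to 12.8 ± 0.874 CPM (-4.06), each with an adjusted p of 0.0353. In XY, the claudin gene Cldn6 rose from 0 to 51.7 CPM, at least 593-fold (adjusted p = 0.0275). By share of cells, each of these genes moved the same way in the other sex. XY ECKO embryos had Bin2 in 16 of 18 and 11 of 18 cells (Controls 3 of 13 and 2 of 22). They had Jak3 in 7 of 18 and 7 of 18 (Controls 12 of 13 and 17 of 22). Plin3 was in 4 of 18 and 3 of 18 (Controls 0, which allows up to 23.1% and 13.6%). XX ECKO embryos had Cldn6 in 11 of 13 and 6 of 13 cells (Controls 2 of 14 and 4 of 16). Stra8 stood at 286 and 147 CPM in XX ECKO embryos and 5.09 and 0.0368 CPM in XX Controls (log2 fold change 6.40, adjusted p = 0.185). In XY ECKO embryos it stood at 4.01 and 25.9 CPM, at least 187-fold above Controls with no count (adjusted p = 0.503). In XX, Nanog (-2.69, adjusted p = 0.253), Pou5f1 (-2.49, adjusted p = 0.299) and Sycp3 (2.82) did not pass, and in XY neither did Pou5f1 (-2.51, adjusted p = 0.719) or Nanog (-0.38). Dazl (0.35 in XX, 0.45 in XY), Ddx4 (0.20 and -0.34) and Sox2 (-0.52 and -0.26) did not pass in either sex.

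By list at E12.5, no member was called over all genes tested. Hox genes (20 tested, 5 higher adjusted over the list alone) and other developmental transcription factors (73 tested, 7 higher and 3 lower adjusted over the list alone) shifted up in XX, with a camera adjusted p of 2.8e-07 each. Both held with an estimated correlation (adjusted p = 0.0321 each), and they were the 2 calls of any comparison that did. In XY they shifted up too (camera adjusted p = 3.8e-05 and 0.000293, 2 higher, and 2 higher and 1 lower, adjusted over the list alone), with an adjusted p = 0.0631 each with an estimated correlation. Interstitial marker sums moved the same way, with 275 and 608 CPM in XX ECKO embryos against 23.6 and 151 in XX Controls, and 194 and 276 CPM in XY ECKO embryos against 34.9 and 119 in XY Controls. In XX, pluripotency genes shifted down (39 tested, 1 higher and 13 lower adjusted over the list alone, camera adjusted p = 9.6e-06, adjusted p = 0.0782 with an estimated correlation). Meiosis genes shifted up in XX (44 tested, 3 higher adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.220 with an estimated correlation) and in XY (0 adjusted over the list alone, camera adjusted p = 0.00736, adjusted p = 0.184 with an estimated correlation). Supporting cell markers shifted up in XX (16 tested, 4 higher adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.0782 with an estimated correlation), as did retinoic acid and BMP response genes (22 tested, 1 higher adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.250 with an estimated correlation). Proliferation genes shifted down in XX (camera adjusted p = 0.00796, adjusted p = 0.250 with an estimated correlation) and XY (camera adjusted p = 0.00736, adjusted p = 0.293 with an estimated correlation), with 0 adjusted over the list alone in both. Imprinted genes (46 tested, 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00736, adjusted p = 0.293 with an estimated correlation) and interstitial markers (13 tested, 1 higher adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.190 with an estimated correlation) shifted up in XY. All 127 cells carried at least 3 germ cell markers, and 3 cells, all in ECKO embryos, carried at least 2 markers of another cell type.

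None of the 4 genes called at E12.5 kept the call with germ-marker cells alone, an alternative added after seeing the data (adjusted p = 0.0561 for Plin3 and Bin2, 0.0585 for Jak3, 0.147 for Cldn6), or with each sex fitted alone (adjusted p = 0.228 for Plin3 and Jak3, 0.175 for Bin2, 0.144 for Cldn6). The counts moved with each embryo left out. With the embryos of a group named in table order, the XX count of 3 became 56 and 192 without the first or second XX Control embryo, 80 and 46 without the first or second XX ECKO embryo, 241 and 202 without the first or second XY Control embryo, and 107 and 114 without the first or second XY ECKO embryo. The XY count of 1 became 46, 53, 3, 5, 16, 16, 7 and 11 in the same order. A group left with 1 embryo is assumed in those fits to vary like the others, and DESeq2 called 910 genes in XX and 327 in XY. The difference between the sexes was called for 0 genes in edgeR, with 681 at an unadjusted p under 0.05 (698 expected) and 135 in DESeq2. Its count was 3 and 37 without the first or second XX Control embryo, 4 without the second XX ECKO embryo, and 5 and 10 without the first or second XY Control embryo. The smallest adjusted p, 0.502, belonged to 5 genes, among them Palm3 (difference of log2 fold changes 13.95, SE 2.18), more positive in XX, and Cldn6 (-10.60, SE 1.53), more positive in XY. The XY Controls had no Cldn6 count, so the size of its fitted difference rests on that 0 and is not a finite estimate. Cldn6 was present in 11 of 13 and 6 of 13 XX ECKO cells and in 11 of 18 and 8 of 18 XY ECKO cells.

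E13.5 XY germ cells were sampled when male germ cells normally enter mitotic arrest. They showed the largest count of the main fits, with 604 of 12336 genes called, 369 higher and 235 lower. With the replicate number as a block their count fell below that of E11.5 XY. Nanos2, an RNA-binding gene of male germ cell fate, rose from a mean of 0.858 CPM (range 0.122 to 2.48, n = 4) to 35.6 CPM (range 2.03 to 52.4, n = 3), a log2 fold change of 5.30 (adjusted p = 0.0296). Zbtb16, a spermatogonial transcription factor, rose from 0.321 to 74.1 CPM (7.77), Tex101, a germ cell surface protein gene, from 0.736 to 108 CPM (7.06), Taf7l, a germ cell TFIID subunit gene on the X, from 0.947 to 97.1 CPM (6.79), and Tdrd1 from 61.7 to 579 CPM (3.23). Among the largest increases, Nptx1 (at least 234-fold), Lrrc15 (at least 125-fold), the interferon-inducible GTPase gene Igtp (at least 122-fold), the immunoproteasome gene Psmb9 (at least 104.7-fold), Foxd1 (at least 99.4-fold), Sytl4 (at least 89.8-fold) and the mesenchymal transcription factor gene Snai1 (at least 83.7-fold) had no count in Controls, and Hoxc12 had a log2 fold change of 9.11. The largest decreases were in Pdk4, a regulator of pyruvate use (-7.73), Csrnp3 (-7.24), Shisa7 (-7.21), Aif1l (-7.15), Siglecf (-6.73), the desmosome gene Dsg2 (-6.59), Abcc2 (-6.41) and the pro-apoptotic gene Bak1 (-5.59).

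Germ cell lists shifted up in E13.5 XY. Of 29 male germ cell differentiation genes, 13 rose over all genes, among them Zbtb16, Tdrd1, Mael and Ccnd2 (3.93), and 16 rose and 4 fell adjusted over the list alone (camera adjusted p = 7.6e-05, adjusted p = 0.0846 with an estimated correlation). Of 35 genome defence and late germ cell genes, 11 rose and 1 fell, and adjusted over the list alone 16 rose and 2 fell (camera adjusted p = 0.000225, adjusted p = 0.236 with an estimated correlation). Taf7l, Mageb4 (from 6.65 to 161 CPM, 4.61) and Mael, a piRNA pathway gene (from 85.7 to 379 CPM, 2.15), were among them. Of 42 meiosis genes, 6 rose, among them Tex101, Tex12 (3.17), Sycp1 (from 52.7 to 205 CPM, 1.96) and Mael, and adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.00350, adjusted p = 0.150 with an estimated correlation). Sycp3 (54.4 and 133 CPM, adjusted p = 0.248), Dazl (-0.55), Ddx4 (0.15) and Dnmt3l (4.65, adjusted p = 0.0987) did not pass. Stra8 was too low to be tested, at 1.07 to 2.58 CPM in ECKO and 0 to 0.399 CPM in Controls.

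Pluripotency and proliferation genes shifted down in E13.5 XY. Of 38 pluripotency and early PGC genes, Dppa2 (from 96.6 to 18.8 CPM, -2.36) and Prdm14 (from 56.9 to 12.6 CPM, -2.18) fell, and 6 fell adjusted over the list alone (camera adjusted p = 7.6e-05, adjusted p = 0.236 with an estimated correlation). Nanog (-1.25, adjusted p = 0.197), Sox2 (-1.08) and Pou5f1 (-0.75) did not pass. Of 33 proliferation genes, the ribonucleotide reductase gene Rrm2 (-2.67), the mitotic kinase gene Plk1 (-1.75) and the replication licensing genes Mcm2 (-1.22) and Mcm4 (-1.16) fell, and adjusted over the list alone 1 rose and 9 fell (camera adjusted p = 1.2e-07, adjusted p = 0.236 with an estimated correlation). Of 6 cell cycle inhibitors, Cdkn1c rose (2.68) on both scales (camera adjusted p = 0.945). The p53 list (25 tested, camera adjusted p = 0.146), the dissociation stress list (13 tested, camera adjusted p = 0.945) and the Rhox list (8 tested, camera adjusted p = 0.945) had no member called over all genes. Adjusted over the list alone 0 p53, 0 stress and 2 Rhox genes passed, the last 1 higher and 1 lower.

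Hox genes rose most among the lists at E13.5 XY. Of 10 tested, 5 rose over all genes, among them Hoxc12 (9.11), Hoxd9 (7.72), Hoxd8 (7.04) and Hoxc13 (5.10), and 9 rose adjusted over the list alone (camera adjusted p = 9.1e-09, adjusted p = 0.0846 with an estimated correlation). The summed CPM of the Hox list was 7.65 ± 7.59 in Controls (n = 4) and 146 ± 59.2 in ECKO (n = 3). Of 45 other developmental transcription factors, Foxf1 (8.11), En1 (6.91), Barhl2 (5.46) and Six2 (2.84) rose, and adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.0169, adjusted p = 0.236 with an estimated correlation). Retinoic acid and BMP response genes (14 tested) shifted up with no called member on either scale (camera adjusted p = 0.00350, adjusted p = 0.168 with an estimated correlation). Of 14 genes of the DNA methylation machinery, Tet3 (4.52), Dnmt3b (3.45) and Dnmt3a (1.64) rose, and adjusted over the list alone 4 rose and 4 fell (camera adjusted p = 0.624). Of 41 imprinted genes, Rian (from 3.32 to 52.1 CPM), Peg10 (3.96), Grb10 (3.20) and Cdkn1c rose and Peg3 fell, from 1076 to 243 CPM (-2.15), and adjusted over the list alone 7 rose and 3 fell (camera adjusted p = 0.583). Interstitial markers shifted up (12 tested, camera adjusted p = 0.00454, adjusted p = 0.236 with an estimated correlation), with Tagln (6.21), Krt19 (5.65) and Pdgfra (4.65) higher on both scales. The abundant mesenchymal transcripts Vim, Col1a2 and Col3a1 together stood at 27.8 ± 15.1 CPM in Controls and 8.21 ± 1.61 in ECKO. Supporting cell markers (12 tested, camera adjusted p = 0.511) had no called gene over all genes and 1 higher adjusted over the list alone. Their sum ran from 56.1 to 335 CPM in Controls and from 134 to 185 in ECKO. Endothelial and blood lists had 4 and 1 tested members, none called by edgeR and too few for camera. The summed endothelial markers were nonetheless higher in each ECKO library (20.6, 40.6 and 48.0 CPM) than in each Control (11.7 to 16.3 CPM).

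**Figure D4:**
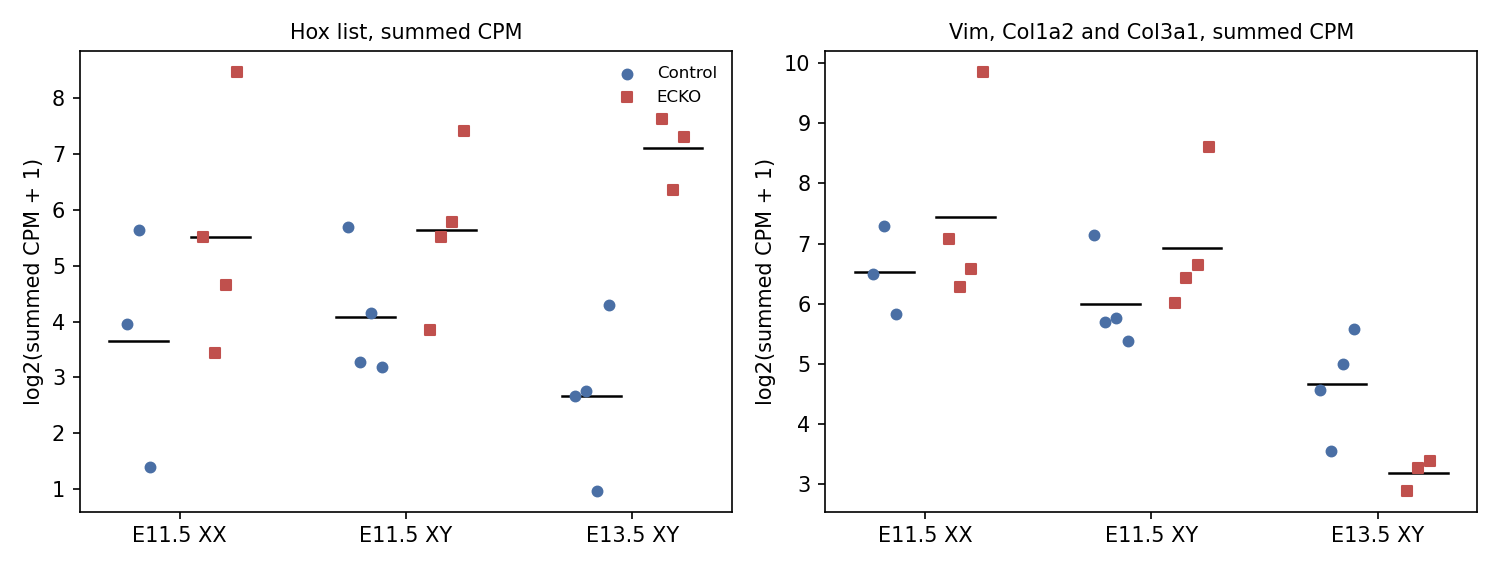
Summed CPM of the Hox list (left) and of Vim, Col1a2 and Col3a1 (right) in each bulk library, as log2 of the sum plus 1, by sex and stage. Circles are Controls, squares are ECKO and horizontal lines mark the mean of the plotted values. At E13.5 XY the Hox sum is 81.5 to 198 CPM in ECKO and 0.945 to 18.6 in Controls.

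The count at E13.5 XY moved to 162, 309, 94, 2141, 99 and 108 when Control 1, Control 2, Control 4, ECKO 1, ECKO 2 or ECKO 3 was left out, and DESeq2 called 1696 genes. Of the 51 named genes called, 41 lost the call under another test, filter or setting and 42 in at least 1 fit with a library left out, among them Nanos2 (adjusted p = 0.0796, 0.0967, 0.110 and 0.111 without Control 1, Control 4, ECKO 2 or ECKO 3), whereas Zbtb16, Taf7l, Tdrd1, Tex101, Mageb4, Ccnd2 and Rrm2 kept it under every alternative run.

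Between E11.5 and E13.5 in XY, 27 genes rose at both stages, 4.02 expected (Fisher's exact p = 2.8e-15), among them Tdrd1, Ccnd1, Ccnd2, Cdkn1c and Dnmt3b, and 15 fell at both, 1.56 expected (Fisher's exact p = 2.9e-11). Of the genes higher at E11.5, 87.0% had a positive fold change at E13.5. The test of the difference between stages called 173 of 14447 genes. The effect was more positive at E13.5 for 71 genes, among them Tex101 (difference of log2 fold changes 6.49), the chromatin remodeller gene Chd3 (3.01), the proton pump gene Atp6v1b2 (2.43), Rpl22l1 (1.97) and Tmsb10 (1.96). It was more negative at E13.5 for 102, among them Dsg2 (-7.11), Aif1l (-6.39), Lrrn4 (-3.59), Srgap3 (-3.35) and Heg1 (-2.79). Without E11.5 XY Control 1 to 4 in turn the count was 52, 34, 55 and 46, and without E11.5 XY ECKO 1 to 4 it was 37, 54, 30 and 74. Without E13.5 XY Control 4 it was 84, and without E13.5 XY ECKO 1, 2 or 3 it was 1267, 73 and 53. With the replicate number as a block far fewer genes were called, and Rpl22l1 and Tmsb10 lost the call.

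The X to autosome ratio asks whether dosage of the X changed with loss of EED. At E13.5 XY it was -0.545 ± 0.131 (SD, n = 4) on the log2 scale in Controls and -0.263 ± 0.0899 (n = 3) in ECKO, a difference of 0.282 with each ECKO library above each Control. The two-sided exact permutation p was 0.0571, the smallest this design allows, and 0.286 after adjustment over the 5 ratios. At E11.5 XY the difference was 0.0295 (two-sided exact permutation p = 0.657), and it was -0.0318 when ECKO 4 was left out. At E11.5 XX the ratios were -0.290 ± 0.0960 (n = 3) and -0.190 ± 0.0823 (n = 4) (exact permutation p = 0.229, smallest possible 0.0571), with a difference of 0.0174 without Control 3 and 0.151 without ECKO 1. At E12.5 the differences were 0.365 in XX and 0.144 in XY (exact permutation p = 0.333 each, the smallest possible with 2 embryos against 2). The XX difference was 0.105 without the second ECKO embryo and 0.606 without the first, and the XY difference was 0.0439 without the first Control embryo, 0.0754 without the first ECKO embryo and 0.218 without the second Control embryo. Among genes with a mean of at least 20 CPM the E13.5 difference was -0.00385, and those of E11.5 XY, E11.5 XX and E12.5 XY turned negative as well. As a list, 456 X-linked genes at E13.5 XY were not called by camera (adjusted p = 0.310), with 41 genes higher and 15 lower over all genes and 52 and 28 adjusted over the list alone.

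**Figure D5:**
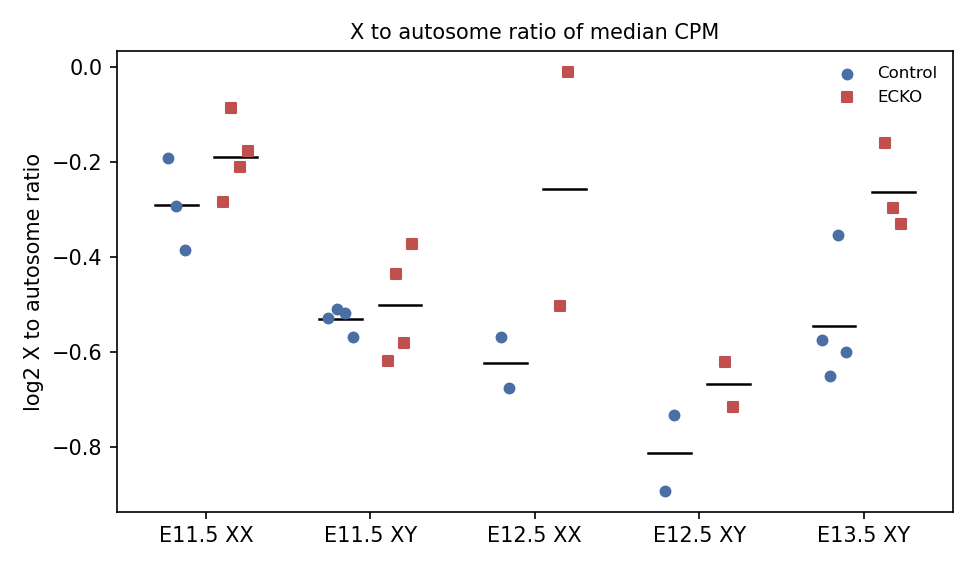
Log2 ratio of the median CPM of X-linked genes to that of autosomal genes in each bulk library or E12.5 embryo, by sex and stage. Circles are Controls, squares are ECKO and horizontal lines mark the mean. At E13.5 XY the means are -0.545 in Controls and -0.263 in ECKO.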

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

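The tests of somatic cells at E13.5, for the Hox genes and for the germ cell differentiation genes, the comparison with all genes higher in ECKO, and the over-representation of X-linked genes were chosen only after those results had been seen.

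Hox and other developmental transcription factor genes were higher in ECKO at E12.5 and at E13.5, by lists whose calls held with an estimated correlation in E12.5 XX alone (adjusted p = 0.0631 each in E12.5 XY, 0.0846 and 0.236 in E13.5 XY), which may reflect loss of repression by PRC2, somatic cells in the sorted samples, or more genes detected per cell. In E12.5 cells with germ cell markers and at most 1 marker of another type, thinned to equal depth, the XX ECKO embryos held 10.96 of these genes per cell on average (14.9 in the first) against 6.14 and 6.06 in Controls, and the XY means were 9.44 and 6.93. The lower of the ratios by sex, 1.36, lay between the bounds set beforehand for somatic cells. These bounds were under 1.2 if somatic cells were the cause and over 1.5 if not. The first embryo carried the XX value (1.15 for the second alone), so that test stays open. The ratio divided by that of all genes detected, at least 1.42 in both sexes, argues against a gain in detection alone. The first ECKO embryo carried most of its XX value, 1.73. The second held 7 of these genes per cell among 4150 detected, against 6.14 and 6.06 among 4521 and 4863 in Controls. At E13.5 the sum of Vim, Col1a2 and Col3a1 in ECKO was 0.296 of that in Controls, at 8.21 CPM beside a Hox sum of 146. In the somatic-rich E11.5 ECKO 4 libraries that sum exceeded the Hox sum (917 and 353 CPM in XX, 390 and 171 in XY). These values argue against somatic cells like those of the ECKO 4 libraries, rich in these transcripts, as the whole cause at E13.5. The sum leaves out Col1a1, which rose, so its fall depends on the genes chosen. The interstitial list moved the other way there (camera adjusted p = 0.00454, adjusted p = 0.236 with an estimated correlation), as did the endothelial sum (20.6 to 48.0 CPM in ECKO, 11.7 to 16.3 in Controls), with Col1a1 at 4.53 to 20.96 CPM in ECKO and 0.388 to 4.91 in Controls and Pdgfra at 5.63 to 35.0 and 0 to 1.92, so a somatic share, or derepression of these genes too, stays open in part, as it does at E11.5.

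Germ cell differentiation genes were higher in E13.5 XY ECKO, by 3 lists whose calls were lost with an estimated correlation (adjusted p = 0.0846, 0.236 and 0.150), which could be an earlier start of the course that Controls follow, a separate derepression, or a shift in cell types. With the Controls divided so that 2 were compared with ECKO and 2 with E11.5, 32 to 41 members were higher in ECKO at an unadjusted p under 0.05 and a log2 fold change over 1, and on average 60.9% of them rose in Controls with stage (57.5 to 67.6 over 6 divisions), between the bounds of 60 and 80 set beforehand, so an advance along that course stays open for these genes. Of all genes higher by the same rule 38.3% rose in Controls against 48.5% of other genes. This cannot tell against such an advance. Genes picked as low in E13.5 Controls tend not to rise by then, and genes that start after E13.5 need not. Over all 96 tested members, the median level relative to that of Ddx4, a general germ cell gene, was higher by 0.86 in ECKO. This is on the log2 scale, with a pooled SD of 0.33 and each ECKO library above each Control. Dazl, another such gene, had a log2 fold change of -0.55. A larger germ cell share of the sample would raise both genes with the members, so these values argue against it as the cause. Ddx4 and Dazl are themselves among the 96, and their values had been seen before the test was written. The Controls of the 2 stages come from separate tables, so their comparison may also carry differences in preparation, which were not tested.

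The X to autosome ratio was higher in E13.5 XY ECKO, though not past the threshold (exact permutation p = 0.0571, 0.286 adjusted over the 5 ratios). This might reflect a change of the whole X, a few X-linked gene families, or the expression level of X-linked genes. Without multi-copy families and unnamed gene models of the X, 0.220 of the difference was left (0.0622 of 0.282). Most of it thus depended on these genes, and a real rise of the families would give the same value. Such genes were kept among the autosomes, and no removal of other X-linked genes was compared, so the families cannot be named as the cause. The median log2 fold change of X-linked genes, 0.20, lay within the middle 95% of autosomal sets matched for level (-0.0302 to 0.228), and the difference was 0.139 at 5 to 20 CPM (exact permutation p = 0.400) and -0.00385 above (exact permutation p = 0.971). X-linked genes outside the families were nonetheless over-represented among the higher genes (24 of 384, against 312 of 11134 autosomal genes outside them, odds ratio 2.31, Fisher's exact p = 0.000494). A change of the X beyond the families, a rise of the families and the expression level of X-linked genes therefore all stay open.

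Other splits of the same libraries were run to see whether chance could be excluded. In E11.5 XY, 1 of 35 splits, the real one, reached the 266 genes (highest other 7) and the 12 lists (highest other 10). This is the smallest share that 35 splits allow, and several such tests were run. It makes chance less likely for both but does not exclude it, and the same holds for the gene counts of E11.5 XX and E13.5 XY. With an estimated correlation 0 of these lists in E11.5 XY were called (smallest adjusted p = 0.124). In E11.5 XX, 1 of 35 reached the 19 genes (highest other 7), but 15 of 35 reached the 6 lists (highest other 10), so chance was not excluded for the lists. In E13.5 XY, 1 of 35 reached the 604 genes (highest other 0), and 2 of 35 reached the 9 lists (highest other 9), so chance was not excluded for those lists. For the difference between sexes at E11.5, 100 of 100 drawn splits reached the count of 0 (highest other 150), as any split must, so this says nothing of chance. For the difference between stages, 2 of 100 reached 173, and the other one called 761. That split kept the real groups at E13.5 and mixed genotypes at E11.5, so the structure it points to includes the E13.5 difference itself, and no other structure among the libraries was shown.

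In 8 of 40 tests, which took several measures in each group of 4 libraries, 1 library stood apart by Dixon's test. Chance alone sets a library apart in about 1 in 20 groups, but these tests are not independent, since the 8 fall in 4 libraries. In E11.5 XX ECKO 4, Xist stood at 709 CPM (others 77.7 to 162), interstitial markers at 1416 (others 128 to 255) and endothelial markers at 497 (others 58.3 to 72.6). In E11.5 XY ECKO 4, interstitial markers stood at 559 CPM (others 109 to 142) and endothelial markers at 331 (others 44.5 to 88.2). In E11.5 XY Control 1, interstitial markers stood at 249.9 CPM (others 61.1 to 81.4) and blood markers at 384 (others at most 22.5). In E13.5 XY Control 2, Stra8 stood at 0.402 CPM of total counts, and at 0 in the other Controls, where any count at all sets a library apart, so this test could not come out otherwise. The groups of 3 libraries, E11.5 XX Control and E13.5 XY ECKO, were not tested in this way. In log2 CPM, E13.5 XY ECKO 1 correlated with ECKO 3 at 0.759 and with ECKO 2 at 0.803. ECKO 2 and ECKO 3 correlated at 0.878.

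The effect of ECKO differed between E11.5 and E13.5 in XY for 173 genes by the test of the difference itself. The named ones were Tex101 (6.49), Chd3 (3.01), Atp6v1b2 (2.43), Rpl22l1 (1.97), Tmsb10 (1.96), Dsg2 (-7.11), Aif1l (-6.39), Lrrn4 (-3.59), Srgap3 (-3.35) and Heg1 (-2.79), as differences of log2 fold changes.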

How the results depend on the processing

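No named gene that was called turned its direction under any alternative, but most counts depended on the test, the filter and single libraries, and the cause was not tested. With RLE size factors the counts stayed within 1.5 times those reported. The smallest library (415291 counts) is in E11.5 XX, and no alternative thinned the bulk libraries. The replicate block at E12.5 was not run, since the embryo codes of the table could not be matched to the numbered labels, and neither was a regrouping of the cell with conflicting labels, which could not be identified. Alternatives added after seeing the data were germ-marker cells alone, leaving out the libraries rich in somatic markers, and leaving out the XX ECKO cells numbered 24.

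DESeq2 called 771 genes in E11.5 XY, 315 in E11.5 XX, 1696 in E13.5 XY, 910 in E12.5 XX and 327 in E12.5 XY, and 1, 831 and 135 for the differences by sex at E11.5, by stage and by sex at E12.5. Without the filter on low counts edgeR called 457, 217, 1268, 566 and 150 genes in the same 5 comparisons, 306 by stage and 84 by sex at E12.5. With the replicate number as a block the counts were 151 in E11.5 XY, 37 in E11.5 XX, 68 in E13.5 XY and 17 by stage, where Rpl22l1 (adjusted p = 0.0848) and Tmsb10 (adjusted p = 0.0769) lost the call. With an estimated correlation 0 lists were called in E11.5 XY, 0 in E11.5 XX, 0 in E13.5 XY, 2 in E12.5 XX and 0 in E12.5 XY. At E12.5, 6 genes were called in XX from all cells. With cells thinned to 50000 counts 1 gene was called in XX and 0 in XY. With germ-marker cells alone, added after seeing the data, 0 were called in XX and 0 in XY. With each sex fitted alone 0 were called in XX and 0 in XY. Without the XX ECKO cells numbered 24 the counts were 4 in XX and 1 in XY. The count by stage was 149 without E11.5 XY ECKO 4 and E13.5 XY Control 3, and that by sex at E11.5 was 0 without both ECKO 4 libraries.

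With 1 library or embryo left out, genes called ran from 64 to 333 in E11.5 XY, 0 to 26 in E11.5 XX, 94 to 2141 in E13.5 XY, 46 to 241 in E12.5 XX and 3 to 53 in E12.5 XY, lists in E11.5 XX from 3 to 9, and differences from 0 to 1 by sex at E11.5, 30 to 1267 by stage and 0 to 37 by sex at E12.5. The X to autosome difference at E11.5 XY ran from -0.0318 to 0.0572. At 20 CPM or more that difference was -0.0959 in E11.5 XY, -0.0523 in E11.5 XX, -0.00385 in E13.5 XY and -0.0138 in E12.5 XY. By X-linked share of counts it was -0.0415, -0.0181, -0.0185 and -0.00172 in E11.5 XY, E11.5 XX, E12.5 XX and E12.5 XY, and the cause was not tested.

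Log2 fold changes that turned were all of genes not called. In E11.5 XY, Ddx4 stood at -0.0138 with no filter and, with the replicate block, Dazl at -0.412 and Ddx4 at -0.0146. With thinned cells Ddx4 stood at -0.179 in E12.5 XX, Dazl at -0.200 and Sox2 at 0.134 in E12.5 XY. With 1 library left out, E11.5 XY ran from -0.483 to 0.461 for Dazl, -0.233 to 0.133 for Ddx4 and -0.0521 to 0.979 for Sycp3, and E11.5 XX from -0.0959 to 0.492 for Pou5f1, -0.381 to 1.35 for Sycp3 and -0.0639 to 3.07 for Xist. E12.5 XX ran from -0.167 to 1.17 for Dazl, -0.271 to 0.913 for Ddx4 and -1.13 to 0.0244 for Sox2, and E12.5 XY from -0.124 to 11.2 for Cdkn2a, -0.317 to 0.935 for Dazl, -1.03 to 1.11 for Ddx4 and -1.94 to 0.325 for Nanog.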

Other observations

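X-linked genes were over-represented among the genes that rose in E13.5 XY ECKO, in a test added after the counts of X-linked calls had been seen. Of 456 X-linked genes tested, 41 rose (8.99%), against 328 of 11847 autosomal genes (2.77%), an odds ratio of 3.47 (Fisher's exact test, p = 2.8e-10). Genes of this set, chosen after its values were seen, include the RNA export gene Nxf2 (log2 fold change 8.49), Xlr5c (8.42), Pramel3 (7.76), the placental homeobox gene Esx1 (7.08), Nxf3 (7.01), Elf4 (5.88), the deacetylase gene Hdac6 (3.53) and the Polycomb-linked genes Scml2 (1.26) and Bcor (1.24). The lower genes held 15 X-linked ones (3.29%) against 219 autosomal ones (1.85%, Fisher's exact p = 0.0348, 0.104 adjusted over the 6 tests). Within multi-copy families and unnamed models 17 of 72 X-linked genes rose, against 16 of 713 autosomal genes (odds ratio 13.4, Fisher's exact p = 1.3e-10). Those autosomal genes were picked by the same symbol patterns and need not be families like those of the X. Outside them 24 of 384 X-linked genes rose, against 312 of 11134 autosomal genes (odds ratio 2.31, Fisher's exact p = 0.000494). At E11.5 the higher genes held 9 of 460 X-linked genes in XY (Fisher's exact p = 0.432) and 0 of 378 in XX, where edgeR called 15 genes higher and the exact p was 1.

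Among E12.5 XX ECKO cells, a hypothesis written before the test was that cells with Stra8 carry less Pou5f1 than cells of the same embryo without it. It could not be tested, since 1 XX ECKO cell lacked Stra8.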
